A study of Drosophila melanogaster with 8 samples.

How the data were processed

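The data are RNA-seq profiles of macrophages (hemocytes, the blood cells that take up debris and microbes) sorted by flow cytometry from Drosophila melanogaster embryos. Per the labels' protocols, stage 11 embryos kept at 29°C were dissociated, mCherry-labelled cells were sorted, and polyA RNA was sequenced with 50 base reads. The sample titles place 4 libraries in the wild type (WT) group and 4 in the CG9005 mutant group. The genotype field holds the same text for both groups, so the groups were taken from the titles. The group means that the authors deposited match that grouping. A developmental stage field counts up from 11 to 18 across the 8 libraries, while the growth protocol gives stage 11 for both genotypes. Stage 11 is used here, and the counting field enters only as an alternative covariate. It runs from 11 to 14 in WT and from 15 to 18 in the mutant, so it largely follows genotype. Fitting it widens the error of the genotype term, so a call lost with it does not show an effect of stage.

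The deposited tables give transcripts per 1000000 (TPM), 1 column per library over 17494 genes, and each column sums to 1000000. Per the submitters' processing notes, STAR 2.5.1b, HTSeq 0.5.4p3, edgeR, limma and R 3.4.4 were used with genome build BDGP6, without the role of each tool. The strand setting and duplicate handling are not given in the sources used here. The authors also deposited a comparison table with log2 fold changes, p-values and adjusted p-values for 11058 genes. The table was present in 4 identical copies, of which 1 was used. Its group means were the means of the deposited TPM columns.

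Each TPM value multiplied by the gene's union exon length (Ensembl release 115 annotation of BDGP6) was a whole multiple of 1 step per library, within a tolerance of 0.05 reads, for 98.8% to 99.0% of the genes. The recovered depth was 15782569 to 18942789 reads per library. Of the 17494 gene identifiers, 17358 had a union exon length in that annotation and 136 did not. Of those 136, 88 were placed through the RefSeq gene table by their names. All 37 genes of the mitochondrial genome were listed at 0 in every library and were not used. Replicates of a group differed by a chi-square of 39.2 to 122 per gene, far above counting noise, so none was treated as a repeat of another. Nothing in the labels says that the replicates came from separate collections, so the p-values measure the spread between these samples, which may be technical.

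The main test used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend in the variance prior and genotype as the only term. Genes with at least 1 TPM in at least 4 libraries were tested, 7827 in all. With 1 library left out, the minimum applied to 3 of the remaining 7. Adjusted p-values follow Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Fold changes are mutant minus WT on the log2(TPM + 1) scale, which understates the change of genes with low values. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 reads per library. Intervals are at the 95% level, and floors cover counting error only. The design written before the data were examined foresaw a count model as the main test if counts had been given, and as an alternative on reads recovered from normalised values. The values are TPM, so the count model was not the main test. The count model was not run on recovered reads either, although reads could be recovered. Limma's voom on the recovered reads was added after seeing the data. It covers 7761 of the tested genes, since 66 have no exon length and so no recovered reads.

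Before the data were examined, 40 gene lists were fixed, covering mitochondrial and metabolic pathways, translation, secretion, migration, immunity, stress, markers of macrophages and of other embryonic cell types, and stage markers. Of these, 38 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. One list holds 5 genes that the published study named on these same samples. The genes named in the text follow a rule fixed in the same way. It takes CG9005, those 5 genes, up to 13 genes per direction with the largest change among called genes whose groups do not overlap, up to 4 genes per list with the smallest p, w (a common transgene marker) and the neighbours of CG9005. Scores of a list are means of log2(TPM + 1) over its tested members in each library, compared by two-sided exact permutation tests over 70 assignments, which cannot give a p below 0.0286.

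Alternatives were each library left out, the replicate number as a block, the counting stage field as a covariate, quantile normalisation, median centring, other filters and pseudocounts, limma without the trend, array weights, and other thresholds. Chosen after seeing the data were voom, tests restricted to genes off chromosome 2, and a count at an unadjusted p under 0.05. The pipeline was tested on simulated data with 200 genes changed among 7772 tested. It called 5 of 67 genes changed by 1.5-fold, 26 of 67 changed by 2-fold and 51 of 66 changed by 4-fold, and 4.65% of its calls were false. In the simulated list test a list of 30 genes raised by 1.5-fold had a camera p of 2.97e-18, and 4 of 100 random lists fell below 0.05. The simulated genes were drawn independently of each other, so that test does not show the error rate of camera on real lists, whose members are correlated. Positions are on BDGP6, counted from 1. No genome sequence was used, so GC content and sequence similarity between gene copies were not analysed here. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, exact tests and plots.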

Results

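The transcriptomes of FACS-sorted stage 11 macrophages were compared between 4 WT and 4 CG9005 mutant libraries, with 15782569 to 18942789 recovered reads in each. The series title frames the question as a genetic program that raises mitochondrial function during macrophage tissue invasion, and CG9005 (also called atossa) is the gene mutated. Between 8806 and 10506 genes had a value above 0 in a library. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.921 to 0.960 within groups and 0.911 to 0.940 between groups.

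CG9005 itself (FBgn0033638, chromosome 2R, 11619479 to 11640941, minus strand, BDGP6) did not differ detectably between the genotypes. Its mean was 87.8 ± 18.4 TPM in WT and 89.1 ± 12.2 TPM in the mutant (SD, n = 4 each), a log2 difference of 0.03 with a 95% interval of −0.35 to 0.41 (limma adjusted p = 0.973, and exact permutation p = 0.857, two-sided). The WT libraries held 72.9, 79.3, 114 and 84.5 TPM and the mutant libraries 75.0, 103, 94.0 and 84.3 TPM, on a mean of 7502 and 8078 reads. The nearest protein-coding genes were not called either. Egm (chromosome 2R, 11616869 to 11619023) had a log2 fold change of 0.17 (limma adjusted p = 0.912), and CG9003 (11641477 to 11651616) one of −0.08 (limma adjusted p = 0.922). The next genes out, tou and CG34228, had log2 fold changes of 0.51 and 0.22 (limma adjusted p = 0.533 and 0.708). The level of CG9005 mRNA therefore does not check the sample labels, and gene totals do not resolve where along a transcript the reads lie. The eye pigment transporter gene w, which many transgenes carry as a marker, was at 19.2 ± 3.79 TPM in WT and 38.2 ± 8.58 TPM in the mutant (log2 fold change 0.94, SE 0.22, limma adjusted p = 0.0693). All 4 mutant libraries lay above all 4 WT libraries for w, and it passed the threshold without mutant replicate 1, with array weights and with voom.

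The 5 genes named by the published study were all lower in the mutant. CG9253 (porthos, a DEAD-box RNA helicase, chromosome 2L, 21143229 onward) fell from 144 ± 16.8 to 14.0 ± 5.09 TPM, a log2 fold change of −3.33 (SE 0.24, limma adjusted p = 5.93e-05). CG2137, a mitochondrial glycerol-3-phosphate dehydrogenase, fell from 31.2 ± 7.55 to 0.947 ± 0.739 TPM (log2 fold change −4.09, limma adjusted p = 9.74e-05). LKRSDH, the lysine-degrading enzyme, fell from 16.4 ± 4.34 to 0.647 ± 0.160 TPM (−3.37, limma adjusted p = 0.000163). CG9331, a glyoxylate and hydroxypyruvate reductase homologue, fell from 20.7 ± 4.20 to 3.19 ± 1.31 TPM (−2.40, limma adjusted p = 0.00146). The Golgi matrix protein gene GM130 fell 7.98-fold from 27.1 ± 12.1 TPM (log2 fold change −2.59, limma adjusted p = 0.00148). All 5 calls were kept without each library in turn, and with the stage covariate only that of CG9253 was kept. With that covariate CG2137, LKRSDH, CG9331 and GM130 had log2 fold changes of −3.77, −3.04, −2.46 and −3.31. The covariate largely follows genotype, so these lost calls may reflect only a wider error. LKRSDH has no recovered reads, so voom did not test it. The list passed camera (adjusted p = 1.41e-15, and adjusted p = 0.0139 with an estimated correlation), and all 5 members were called whether adjusted over all genes or adjusted over the list alone. The study chose these genes on these samples, so their direction is not independent evidence. All 5 lie on chromosome 2, as CG9005 does. CG9253 overlaps del on the opposite strand and a snoRNA on its own, and CG2137 overlaps CG1598 and Cyt-b5, so reads may be shared there.

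**Figure D1:**
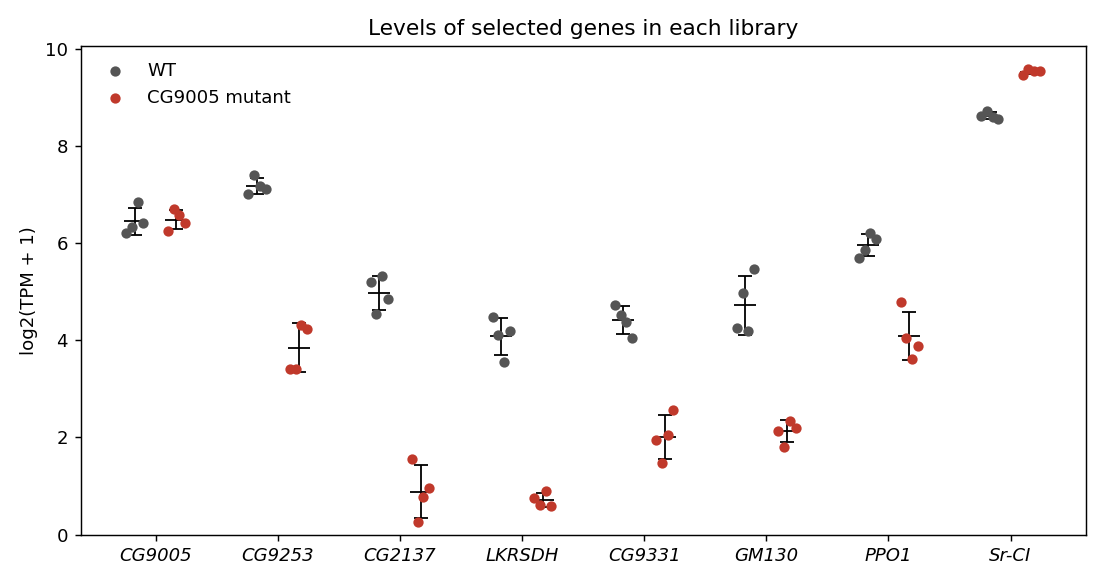
Levels of 8 genes in each library, as log2(TPM + 1) on the vertical axis. Each point is 1 library (grey, WT, n = 4; red, CG9005 mutant, n = 4), and the bars give the mean and SD. CG9005 overlaps between genotypes at means of 87.8 and 89.1 TPM, while all mutant libraries lie below all WT libraries for CG9253, CG2137, LKRSDH, CG9331, GM130 and PPO1, and above them for Sr-CI.

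Across the transcriptome 131 of 7827 tested genes were called (1.67%), 69 higher and 62 lower in the mutant. The median log2 fold change over all tested genes was −0.06. List medians, list scores and counts of members below 0 were not centred on it, while camera compares a list with the other genes. The rise of the noncoding RNA CR40469 (X, 122493 onward) was the largest, from 23.7 ± 7.20 to 15320 ± 3782 TPM (log2 fold change 9.29, SE 0.22, limma adjusted p = 1.20e-09). CG31997 on chromosome 4 rose from 0.190 ± 0.379 to 35.9 ± 14.0 TPM (4.89, limma adjusted p = 9.43e-05), and the noncoding RNA CR45822 from 0.292 ± 0.363 to 26.6 ± 2.20 TPM (4.45, limma adjusted p = 2.16e-05). CG15425 was at 0 in every WT library and reached 13.4 ± 7.37 TPM in the mutant, at least 45.2-fold higher. The noncoding RNA CR45258 (log2 fold change 3.68) and HLH54F, a transcription factor of the visceral muscle lineage (3.51), also rose (limma adjusted p = 0.000560 and 0.00251).

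Among the largest falls, CG31797 went from 13.9 ± 7.30 to 0.112 ± 0.132 TPM (log2 fold change −3.61, limma adjusted p = 0.000818). CG10178, CG34043 and OS9 were at 0 in every mutant library, at least 104-fold, 37.1-fold and 22.4-fold lower than in WT. The pseudogene CR33319 (−3.19), the C-type lectin gene lectin-24Db (−3.01), the Turandot stress gene TotF (−2.92), CG7299 (−2.52) and CG9436 (−2.51) fell as well, with limma adjusted p between 0.00146 and 0.0347. The calls of TotF and CG9436 did not hold when some single libraries were left out. TotF lost its call without any of the 4 WT libraries or mutant replicates 1 and 3 (limma adjusted p 0.0630 to 0.102), and CG9436 without WT replicates 1, 3 and 4 or mutant replicate 3 (limma adjusted p 0.0622 to 0.0808). The tRNA gene tRNA:Trp-CCA-2-2 was higher (log2 fold change 3.87, limma adjusted p = 0.0252), but it belongs to a family of near-identical copies, so its value is uncertain. It lost the call without any library other than WT replicate 3 or mutant replicate 3 (limma adjusted p 0.0670 to 0.0793). OS9, CR33319, TotF and CR45822 overlap another annotated gene on the opposite strand. LKRSDH also overlaps an annotated gene, but its own strand was not known here, so the orientation is open.

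The groups did not overlap for 130 of the 131 called genes, and for 7.77% of all tested genes against 2.86% given by chance. The count of calls fell to 72, 74, 86, 73 and 71 without WT replicate 1, 2 or 4 or mutant replicate 2 or 4. With voom on the recovered reads 88 genes were called, 69 of them among the 131. Of the 36 called genes named here voom tested 35, and 17 kept their call, CG9253, CG2137, CG9331, GM130, PPO1 and Sr-CI among them. The other 18 lost it (limma adjusted p 0.0566 to 0.278), CG31997, CR45258, CG31797 and CG10178 among them. The authors' deposited table holds 64 genes past the same threshold, 39 higher and 25 lower. Of the 64 genes from the authors' deposited table, 55 were tested here, all 55 had the same sign and 48 were called. Only those 48 of the 131 calls here were past the threshold in the authors' table. Sr-CI, IM14, IM1, nrv3, Men, gcm2 and Prosbeta4 were called here but not there. With the counting stage field as covariate 9 genes were called, 6 of them among the 131.

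The called genes were unevenly placed on the chromosomes. Chromosome 2 held 93 of the 131, with 44 of 1390 tested genes called on arm 2L and 49 of 1625 on arm 2R. The other placed chromosomes held 37 calls among 4804 tested genes, 14 on 3L, 13 on 3R, 2 on chromosome 4 and 8 on X. Chromosome 4 had only 68 tested genes, so its rate of 2.94% rests on 2 calls. The call rate was 3.08% on chromosome 2 and 0.770% on chromosomes 3, 4 and X (odds ratio 4.10, Fisher's exact p = 1.99e-14, two-sided). The excess held for higher genes (odds ratio 3.02, Fisher's exact p = 8.72e-06) and for lower genes (odds ratio 5.96, Fisher's exact p = 2.46e-10). Within 2 Mb of CG9005 15 of 324 genes were called and on the rest of the arm 34 of 1301 (Fisher's exact p = 0.0684). Fisher's tests count genes as independent, but some called genes lie side by side, such as CG33509 and ppk13 on 2L. Their p-values may therefore be too small, and they do not measure spread between fly lines.

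**Figure D2:**
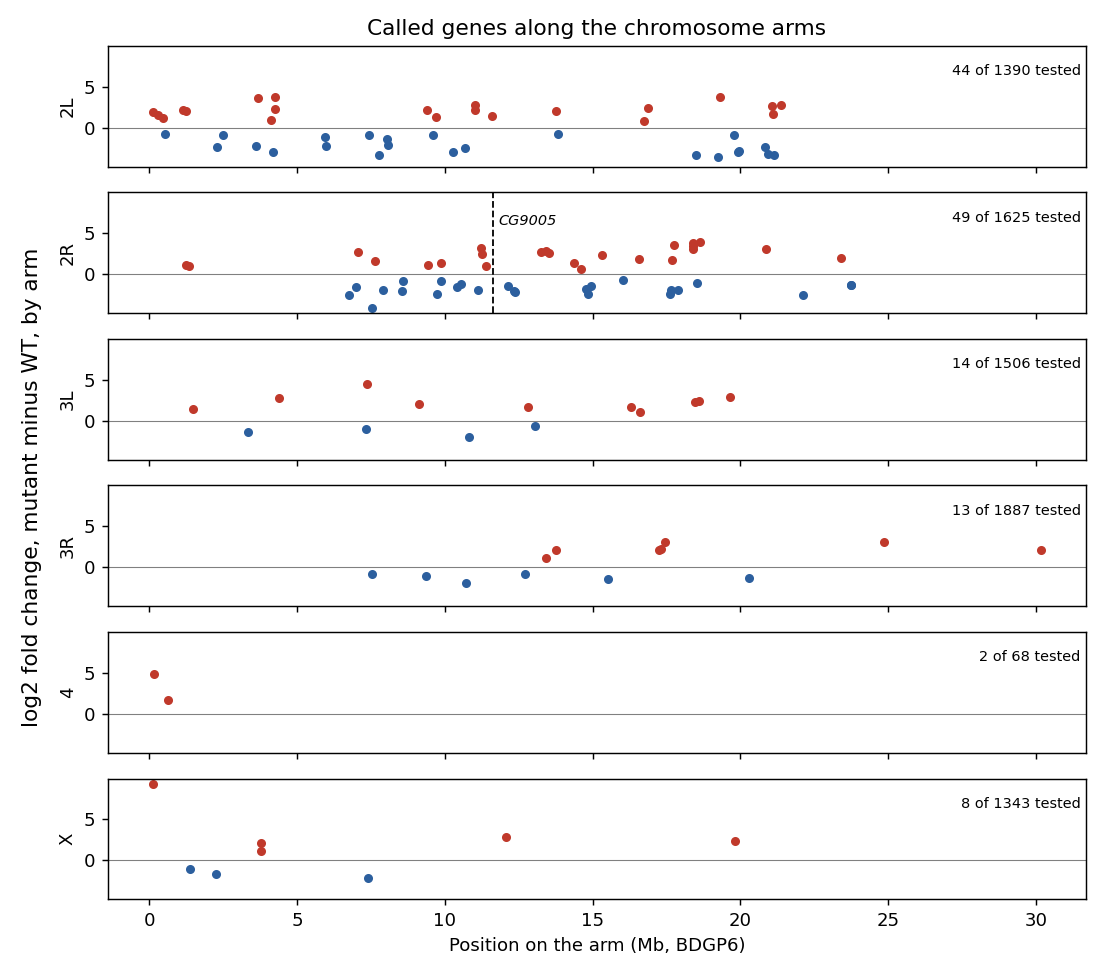
Positions of the called genes along 6 chromosome arms, in Mb on BDGP6 (horizontal axis), against their log2 fold change, mutant minus WT (vertical axis). Each point is 1 called gene (red, higher in the mutant; blue, lower), and the dashed line marks CG9005. The points are densest on 2L (44 of 1390 tested genes) and 2R (49 of 1625) and spread along both arms.

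Of the mitochondrial and metabolic lists, those of complex I and of glycolysis passed camera. Of 32 tested subunits of complex I, the NADH dehydrogenase of the respiratory chain, none was called over all genes and 2 were higher adjusted over the list alone, namely ND-MWFE (83.5 to 128 TPM, log2 fold change 0.62, limma adjusted p = 0.0658) and ND-PDSW (358 to 508 TPM, 0.49, limma adjusted p = 0.0737). The list had 24 members above and 8 below 0, a median log2 fold change of 0.12 and a camera adjusted p of 0.00324, with adjusted p = 0.604 with an estimated correlation. It did not pass among genes off chromosome 2 (median 0.07, adjusted p = 0.142) or with the stage covariate (median 0.04, adjusted p = 0.367). Both ND-MWFE and ND-PDSW passed with quantile normalisation and with median centring. Subunits of complexes II and III, complex IV and ATP synthase, mitochondrial ribosomal proteins and import factors had medians of 0.05, 0.04, 0.09, 0.01 and −0.00 with camera adjusted p of 0.262, 0.472, 0.135, 0.131 and 0.472. Mitochondrial ribosomal proteins passed, as higher, without WT replicate 4 or mutant replicate 1 and with quantile normalisation or median centring (adjusted p = 0.0168, 0.0196, 0.0323 and 0.0377), and ATP synthase without WT replicate 4 and with median centring (adjusted p = 0.0454 and 0.0431). In the tricarboxylic acid cycle list (median 0.18, camera adjusted p = 0.194), Men, the cytosolic malic enzyme, was the 1 called gene of 25 tested and fell from 130 to 70.3 TPM (log2 fold change −0.89, limma adjusted p = 0.0178). Men lost its call without WT replicate 2 or mutant replicate 2 or 4 (limma adjusted p 0.0547 to 0.0715). Glycolysis genes had 13 of 15 tested members above 0, a median of 0.53 and a camera adjusted p of 0.000124, with adjusted p = 0.406 with an estimated correlation. With the strict filter of 10 TPM, which left 6 of them, the median was 0.17 and the list did not pass (adjusted p = 0.105). None of them was called, whether over all genes or adjusted over the list alone. Gapdh1 was at 2.41 TPM in WT and 9.40 in the mutant (limma adjusted p = 0.118), and Pglym78 at 8.37 and 17.4 (limma adjusted p = 0.201). In the amino acid breakdown list (19 tested, median 0.09, camera adjusted p = 0.711) the calls were LKRSDH and CG9331, both lower. Its 10 tested genes off chromosome 2 went the other way and passed as higher (median 0.51, adjusted p = 0.0434).

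No translation or protein handling list passed camera in the main test. The 91 tested cytosolic ribosomal proteins had a median of −0.01 (camera adjusted p = 0.643) and no call, but passed without WT replicate 1 (median 0.03, adjusted p = 0.0210). In the ribosome biogenesis list (34 tested, median −0.04) and the DEAD-box helicase list (26 tested, median 0.02) CG9253 was the 1 called gene, with a camera adjusted p of 0.938 for each list. Translation factors (43 tested) had a median of −0.08 and a camera adjusted p of 0.462. Of 31 tested proteasome subunits Prosbeta4 was called, from 71.0 to 122 TPM (log2 fold change 0.80, limma adjusted p = 0.0420). It kept that call only without WT replicate 3 among the libraries left out (limma adjusted p 0.0639 to 0.149 for the others). Lysosome, autophagy, endoplasmic reticulum and Golgi lists had camera adjusted p of 0.947, 0.761, 0.0624 and 0.331, with medians of −0.05, −0.08, −0.14 and −0.12. The endoplasmic reticulum list, with 16 of 19 tested members below 0, passed without WT replicate 1, without WT replicate 3, with quantile normalisation, without a filter and with array weights (adjusted p = 0.0340, 0.00174, 0.0439, 0.0234 and 0.00813). GM130 was the 1 call among these lists. The 39 tested migration and invasion genes had 30 members below 0, a median of −0.16 against −0.06 over all tested genes, no call and a camera adjusted p of 0.135. Their score lay lower in every mutant library than in every WT library, by a mean of 0.14 (exact permutation p = 0.0286, not adjusted over the lists). Of 38 list scores 6 had that smallest exact p, where chance gives about 1.09, the others being those of the study's genes, crystal cells, gut, late cuticle and humoral immunity. The study's genes were chosen on these samples, and the lists share libraries and some genes. Whether 6 exceeds chance was therefore not tested.

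Some immune peptide genes were called higher in the mutant. IM14 rose from 15.7 ± 9.46 to 136 ± 87.9 TPM (log2 fold change 3.04, limma adjusted p = 0.00700), and Listericin, an antibacterial peptide gene, from 0 in every WT library to 9.02 ± 5.06 TPM, at least 17.2-fold. IM1, IM2 and IM3, immune-induced peptides encoded side by side on 2R, rose from 2.14 to 36.1, from 4.38 to 32.4 and from 4.13 to 31.6 TPM (16.9-fold for IM1, with limma adjusted p = 0.0220, 0.0443 and 0.0413). CG16713 rose from 4.43 to 52.5 TPM (3.67, limma adjusted p = 0.0376). IM1, IM2 and IM3 are related genes, and reads shared between them were not analysed here. IM14 and Listericin kept their calls without each library but lost them with voom (limma adjusted p = 0.0566 and 0.0986) and with the stage covariate (limma adjusted p = 0.540 and 0.185). The other 4 calls did not hold when some single libraries were left out. IM1 lost its call without WT replicate 3 or 4 or mutant replicate 1 or 2 (limma adjusted p 0.0593 to 0.0710), CG16713 without any library but WT replicate 1 and mutant replicate 3 (0.0659 to 0.115), and IM2 and IM3 without any library but WT replicate 1 (0.0538 to 0.148 and 0.0621 to 0.138). Only IM1 and IM2 of these genes belong to the fixed humoral immunity list, while IM14, Listericin, IM3 and CG16713 were named for the size of their rise. The list had 11 of 12 tested members above 0, with 2 called over all genes (IM1 and IM2) and 4 adjusted over the list alone (IM1, IM2, IM23 and PGRP-SD). Its median was 0.77 and its camera adjusted p 0.000118, with adjusted p = 0.371 with an estimated correlation and adjusted p = 0.0569 among genes off chromosome 2.

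Among 23 tested macrophage markers, the scavenger receptor gene Sr-CI rose from 394 ± 20.7 to 739 ± 29.1 TPM (log2 fold change 0.91, SE 0.10, limma adjusted p = 0.000818), and gcm2, a transcription factor gene of the blood lineage, fell from 31.5 to 16.4 TPM (−0.93, limma adjusted p = 0.0429). The gcm2 call was kept only without mutant replicate 3 among the libraries left out (limma adjusted p 0.0821 to 0.149 for the others), and it was lost in 14 of 19 settings. The list had a median of −0.04 but a mean of 0.12 (camera adjusted p = 0.643). That mean was 0.005 without mutant replicate 2 and 0.22 without mutant replicate 3. Crystal cell markers were all below 0 (7 of 7, median −0.39, camera adjusted p = 0.00348, with adjusted p = 0.371 with an estimated correlation and adjusted p = 0.0713 off chromosome 2). The crystal cell list passed with fry, as lower (adjusted p = 0.0355). PPO1, a prophenoloxidase of these melanising cells, fell from 61.8 ± 9.85 to 16.8 ± 6.73 TPM (log2 fold change −1.88, limma adjusted p = 0.00278). PPO2 was at 568 TPM in WT and 437 in the mutant (−0.35, limma adjusted p = 0.508).

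Markers of other embryonic cell types did not move together. Among 15 tested nerve and glia genes, nrv3, a sodium pump subunit, rose from 0.629 to 10.7 TPM (log2 fold change 2.75, limma adjusted p = 0.00557) and Rdl, a GABA receptor, from 1.07 to 7.55 TPM (1.98, limma adjusted p = 0.0203). The nrv3 call was kept without each library but lost with voom (limma adjusted p = 0.0658) and with the stage covariate (limma adjusted p = 0.299). The Rdl call was kept with voom but lost without WT replicate 2 or 4 or mutant replicate 1 or 2 (limma adjusted p 0.0516 to 0.0771). Among 17 muscle genes Mlc2, a myosin light chain, rose from 6.08 to 28.4 TPM (2.09, limma adjusted p = 0.0490), and that call was lost without any library but WT replicate 1 and mutant replicate 3 (limma adjusted p 0.103 to 0.169) and with most other settings. The nerve and muscle lists had medians of 0.18 and 0.37 and camera adjusted p of 0.00759 and 0.00519, with adjusted p = 0.676 and adjusted p = 0.604 with an estimated correlation. The nerve list did not pass without WT replicate 2 (adjusted p = 0.0788), nor the muscle list without mutant replicate 1 (adjusted p = 0.0758), and neither passed with the strict filter, which left 5 and 7 genes (adjusted p = 0.398 and 0.0784). Epidermis, trachea and salivary gland, gut and fat body lists had medians of −0.36, −0.25, −0.38 and −0.36 and no call (camera adjusted p = 0.138, 0.462, 0.194 and 0.356), and germ cell markers one of 0.03 (0.943). The epidermis list passed, as lower, without WT replicate 4 (adjusted p = 0.0166). WT replicate 3 had the highest epidermis and fat body scores, and without it the score differences went from −0.26 to −0.07 and from −0.22 to −0.13 (−0.11 for fat body without mutant replicate 3). The late cuticle list (13 tested) had a median of 0.40 and a camera adjusted p of 0.0115, with adjusted p = 0.366 with an estimated correlation, but its 1 called gene, Acp32CD, belongs to the male accessory gland family and not to the cuticle. Acp32CD rose from 0.114 to 7.05 TPM (log2 fold change 2.81, limma adjusted p = 0.00174). The late cuticle list passed with fry, as higher (adjusted p = 0.0355). It did not pass camera without WT replicate 2, WT replicate 4 or mutant replicate 4 (adjusted p = 0.0987, 0.0579 and 0.0569). It also did not pass without a filter, over 94 genes (median 0.00, adjusted p = 0.369), off chromosome 2 (adjusted p = 0.360), with voom (adjusted p = 0.0769) or with the stage covariate (adjusted p = 0.113). Early patterning genes had a median of −0.17 (camera adjusted p = 0.789).

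Cell cycle genes lay mostly below 0, 23 of 27 tested, with a median of −0.33 and a camera adjusted p of 0.00201, with adjusted p = 0.604 with an estimated correlation and adjusted p = 0.0565 off chromosome 2. None was called singly over all genes or adjusted over the list alone. CycE was at 8.01 TPM in WT and 3.59 in the mutant (limma adjusted p = 0.141). Lists for heat stress, immediate early and JNK targets, oxidative stress, histones and dosage compensation did not pass camera (adjusted p = 0.462, 0.331, 0.462, 0.262 and 0.208). In all, 9 of 38 tested lists passed with the preset correlation, 6 higher and 3 lower, and the list of the study's own genes was the 1 that passed with an estimated correlation.

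**Figure D3:**
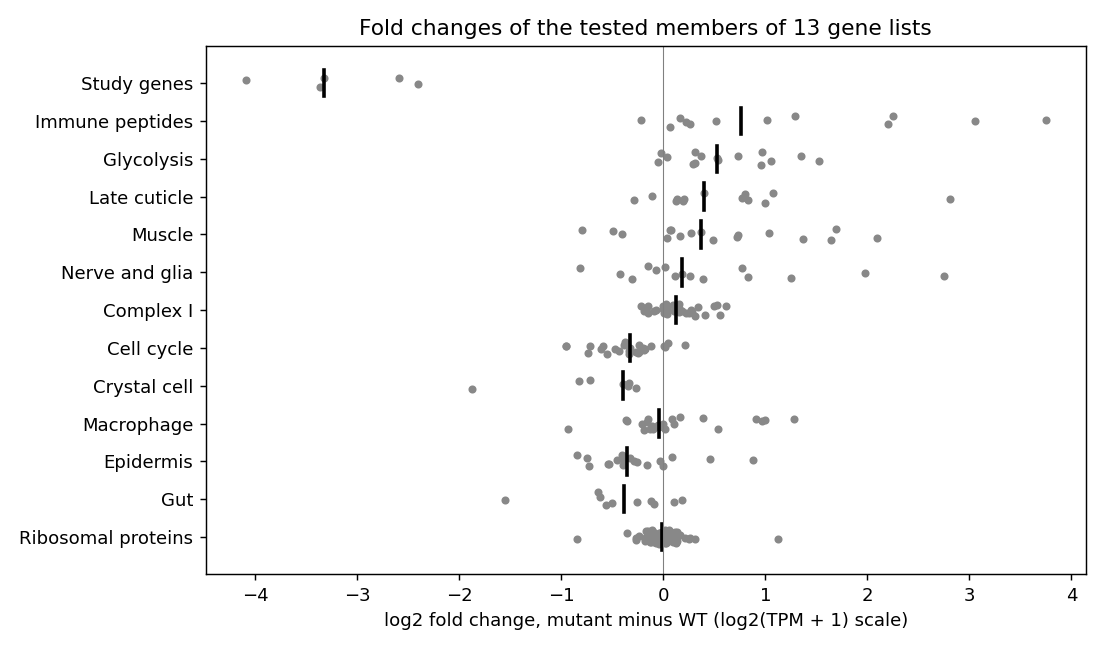
Log2 fold changes, mutant minus WT, of the tested members of 13 gene lists (horizontal axis, log2(TPM + 1) scale). Each grey point is 1 gene, spread vertically for legibility, and each black bar is the list's median. The medians run from −3.33 for the study's 5 genes to 0.77 for immune peptides, with −0.01 for ribosomal proteins and −0.04 for macrophage markers.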

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

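All tests of explanations below were chosen after the results were seen. Of 90 groups of 4 values checked, 10 held a library far from the other 3, where chance gives about 1 in 20. Several concern genes near 0. CG31997 was at 0.758 TPM in WT replicate 3 and at 0 in the other WT libraries, CR33319 at 0.131 TPM in mutant replicate 1 against 0, and Acp32CD at 0.455 TPM in WT replicate 4 against 0. The tRNA gene tRNA:Trp-CCA-2-2 was at 14.1 TPM in WT replicate 3 and at most 1.12 in the others. WT replicate 1 held 14.0 TPM of CG16713 and 14.3 TPM of IM3, against at most 2.04 and 1.62 TPM in the other WT libraries. HLH54F was at 70.7 TPM in mutant replicate 1 and at 29.1 to 35.4 in the other mutant libraries. Among the neighbours of CG9005, tou was at 33.5 TPM in WT replicate 3 against 13.5 to 14.3, CG34228 at 83.8 TPM in WT replicate 2 against 52.9 to 57.7, and CG9003 at 27.0 TPM in WT replicate 4 against 32.2 to 32.9.

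The immune peptide genes IM14 and IM1 were higher in the mutant (log2 fold changes 3.04 and 3.75), while the fixed humoral immunity list, which holds IM1 but not IM14, lost its call with an estimated correlation (adjusted p = 0.371). Fat body cells carried into the sort, a main source of such peptides, stay open: the score of the list of fat body, amnioserosa and yolk markers was lower in the mutant by 0.22 (log2, exact permutation p = 0.229), but the list mixes these tissues and only 8 of its 16 genes were tested. Within it Ance, peb and tup had log2 fold changes of −0.69, −0.72 and −0.98, and the lipoprotein gene apolpp was at 13.3 TPM in WT and 27.1 in the mutant, none of them called over all genes (limma adjusted p 0.117 to 0.540), with 2 lower, Ance and peb, adjusted over the list alone. Genes of chromosome 2 alone remain a possible source: 7 of the 12 tested genes of that immunity list lie there with a median log2 fold change of 1.02, the 5 others had a median of 0.51, and the camera adjusted p among genes off chromosome 2 was 0.0569, so the 2 cannot be told apart on 5 genes. An effect of the genotype itself stays open.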

How the results depend on the processing

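Tests with voom, with genes off chromosome 2 only and at an unadjusted p under 0.05 were chosen after seeing the data. The count model planned for recovered reads was not run, although reads could be recovered, and voom was used on them. CG9005 stayed uncalled in all 19 settings, with log2 fold changes of −0.05 to 0.17 when each library was left out. The 131 calls ranged from 71 to 110 with 1 library left out. They came to 76 without a filter, 75 with the strict filter of 10 TPM, 88 with voom, 22 among genes off chromosome 2, 210 at an adjusted p of 0.1, 756 at an unadjusted p under 0.05 with 1.5-fold and 950 without the fold. Fewer libraries or genes enter some of these, and otherwise the cause was not tested. With the counting stage field as covariate 9 genes were called, 6 of them among the 131. That field is tied to genotype, 11 to 14 in WT and 15 to 18 in the mutant. Calls lost with it may therefore reflect only a wider error of the genotype term. The replicate number as a block gave 52 calls, all 52 among the 131. The numbers do not pair the samples, because deviations of same-numbered libraries correlated at 0.08, −0.15, −0.04 and −0.04 and not every library correlated best with its own number. The 9 lists past camera ranged from 7 to 11 with 1 library left out, and were 5 with the strict filter, 4 off chromosome 2, 3 with fry and 1 with an estimated correlation. With fry the 3 lists were those of the study's genes, crystal cells and late cuticle. Mitochondrial ribosomal proteins turned to a median of −0.32 with the stage covariate (adjusted p = 0.0164), and the cause was not tested. Of 36 called named genes none changed sign in any setting, 24 kept the call without each library, 31 lost it with the stage covariate, 18 with voom and 12 with the block. Of 135 uncalled named genes 9 passed in at least 1 setting. Depth limits genes near the floor of 3 reads, and in simulation 5 of 67 genes changed by 1.5-fold were called.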

Other observations

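All tests below were chosen after the results were seen. The called genes in this paragraph lie outside the fixed lists and the naming rule and were picked after their values were seen. The vesicular monoamine transporter gene Vmat rose from 0.176 to 6.60 TPM, the peptide hormone receptor gene Dh31-R from 1.21 to 13.4 TPM, and the muscle troponin gene TpnC47D from 3.66 to 21.5 TPM (limma adjusted p = 0.00417, 0.00251 and 0.0315). Arc1 rose from 41.3 to 108 TPM and the aldehyde dehydrogenase gene Aldh from 12.3 to 59.3 TPM (limma adjusted p = 0.00138 for each). The photoreceptor channel gene trpl fell from 4.34 to 0.00459 TPM, and Arpc1, a subunit of the actin-nucleating Arp2/3 complex, from 111 to 63.4 TPM (limma adjusted p = 0.00308 and 0.0259). Also lower were the receptor genes CCHa1-R (log2 fold change −1.94), nAChRbeta3 (−0.81) and Or2a (−1.69), with limma adjusted p = 0.0219, 0.0112 and 0.0444.

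Called genes were concentrated on chromosome 2, the chromosome that carries CG9005. In 10000 random sets of genes matched on level and exon length, at most 73 lay on chromosome 2, against 92 of the 129 called genes with a length (permutation p = 0.0001, the smallest the draws can give), which argues against changes placed without regard to chromosome, as regulation of unlinked targets would place them. The draws, like Fisher's tests, treat genes as independent, though some called genes lie side by side. A region around CG9005 alone would leave arm 2L at the rate of the other chromosomes, and 2L was above it (Fisher's exact p = 3.50e-10). A second chromosome of another origin in the mutant line, with sequence differences that act on genes along it, stays open. It needs an excess on both arms and in both directions, and the largest of the 4 Fisher's exact p-values was 0.000418, but that excess prompted the explanation and so does not support it. If it were so, the falls of CG9253, CG2137, LKRSDH, CG9331 and GM130, which all lie on chromosome 2, may come from that chromosome or from the CG9005 mutation, and both stay open for each gene. The same limit applies to every other gene among the 93 called on chromosome 2. These include Sr-CI and nrv3 on 2L, and PPO1, IM14, Listericin and HLH54F on 2R.

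The nerve, muscle and glycolysis lists passed camera as higher and the cell cycle list as lower in the mutant, but none passed with an estimated correlation (adjusted p = 0.676, 0.604, 0.406 and 0.604), and the exact permutation p of their scores was 0.0857, 0.0571, 0.0571 and 0.0571. A smaller share of macrophages in the mutant sort would raise all other cell types alike if the carried-over cells mirrored the embryo, which was not tested. The mutant minus WT differences of all 7 non-blood lists had an SD of 0.37 (log2). That was larger than in any other split of the libraries (exact permutation p = 0.0286, the smallest the design allows, and the same without each library). These lists therefore did not move alike, but their spread was seen before the test was chosen. A smaller share of macrophages stays open, as do more nerve and muscle cells alone. Older mutant embryos cannot be told apart from the genotype. The score of the late cuticle list, from 13 tested genes of 145, was higher in the mutant by 0.61 (exact permutation p = 0.0286). It includes Acp32CD (log2 fold change 2.81), which does not belong to the cuticle, and a score without that gene was not computed. The early patterning list, which should fall with age, had a difference of −0.14 (exact permutation p = 0.486). That difference was −0.02 without WT replicate 3 and −0.23 without WT replicate 4. Age therefore stays open. The cuticle list also missed camera without WT replicate 2, WT replicate 4 or mutant replicate 4 (adjusted p = 0.0987, 0.0579 and 0.0569), without a filter (median 0.00, adjusted p = 0.369), off chromosome 2 (adjusted p = 0.360), with voom (adjusted p = 0.0769), with the stage covariate (adjusted p = 0.113) and with an estimated correlation (adjusted p = 0.366). An effect of the genotype itself stays open and was not tested apart from collection age.

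Other groupings of the 8 libraries bear on both counts. Of the 35 ways to split them into 2 groups of 4, 1, the real one, gave as many as 131 called genes, and the highest of the others was 4. That is the smallest share that 35 splits can give, and the other splits mix the 2 genotypes. It argues against chance for the gene count without excluding it. It cannot tell the genotype from anything else that differs between the groups. For the lists past camera, 8 of the 35 splits gave 9 or more, and the highest of the others was 13, so chance is not excluded for the number of lists.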
